A study of Mus musculus with 12 samples.

How the data were processed

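Placental tissue from mice lacking Grhl2, which encodes a grainyhead-like transcription factor of epithelia, was compared with wild-type tissue at embryonic days 7.5 and 9.5 (E7.5 and E9.5). Per the labels' protocols, the E7.5 samples held tissue of trophectoderm origin, including giant cells, ectoplacental cone and chorion, and the E9.5 samples the placenta, each freed of embryo and uterus. Total RNA was amplified, labelled with biotin and hybridized to Illumina Mouse WG6 BeadChips, per the labels' protocols. There were 12 arrays in 4 groups of 3, described as biological replicates in the series design. The p-values of single genes below therefore measure the spread between these samples. Those of Fisher's exact test take genes as the units, and those of the main test of gene lists compare genes at an assumed correlation. Which embryos or litters went into a sample is not given in the sources used here.

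The values deposited by the authors were linear probe intensities for 45281 probes. Scanner, software, background treatment and normalization are not given in the sources used here. Read from the values, the deposited intensities had been brought to a common distribution separately within each stage. The sorted log2 values of the 6 arrays of a stage differed from their mean by at most 0.00762 at E9.5 and 0.00878 at E7.5. The deposited medians lay at 114.7 to 114.8 for the E9.5 arrays and at 76.26 to 76.30 for the E7.5 arrays, and the lowest values at 58.54 and 45.13. Values never came near 0, so the background was not subtracted down to 0 and differences of dim probes are compressed. Detection p-values, chip positions and scan dates were not used here, and the number of arrays limits the precision.

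Because the array medians differed by 0.59 on the log2 scale, more than the 0.1 allowed for keeping the deposited scaling, log2 values were quantile normalized over all 12 arrays. A floor of 10 before the logarithm touched 0 values. For stage differences near that size, stage and the authors' separate normalization cannot be told apart. No batch is named in the labels, so a batch that ran with stage could not be tested. Probes were named through the GEO platform annotation, and symbols were looked up by gene identifier in a RefSeq table of assembly GRCm38.p6. Of the probes, 34885 had 1 symbol, 18 had several and 10378 had none, and 34807 of the first kind matched the table, with 0 symbols changed. Each gene was represented by its brightest probe, and 9172 of 19057 genes had more than 1 probe. A gene was tested where its highest group mean exceeded the median probe level of 6.52 on the log2 scale (91.5 in linear units), which left 13910 genes. Coordinates are not printed because no genome build is named for the array files.

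Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 1 mean per group, all 12 arrays sharing 1 estimate of the spread), with Benjamini-Hochberg adjustment over all tested genes. Unless another method is named, an adjusted p is limma's, n is 3 arrays per group, and a gene was called changed at an adjusted p under 0.05 with no minimum fold. The comparisons were knockout against wild type at each stage, the difference between those differences (the interaction), and wild type at E9.5 against wild type at E7.5. Differences are given as log2 of knockout minus wild type with their standard error (SE), and group means with their SD.

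Gene lists fixed before the data were examined held 491 genes, of which 396 were tested. The 20 lists covered epithelial junctions, epithelial regulators and membrane proteases, mesenchyme and epithelial-mesenchymal transition (EMT), basement membrane and integrins, syncytiotrophoblast and labyrinth, chorion and trophoblast progenitors, spongiotrophoblast and glycogen cells, trophoblast giant cells, endothelium, erythroid cells, allantois and umbilical mesoderm, decidua, leukocytes and natural killer cells, visceral and parietal endoderm, cell cycle, hypoxia and glycolysis, p53 and integrated stress response, sterol and lipid synthesis, nutrient transporters, and imprinted genes. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 20 lists, and again with an estimated correlation and with fry. A list's own members were also adjusted over the list alone. The main tests, most alternatives and the rule for the genes named were fixed at the same time. The rule took all Grhl2 probes, the 12 largest called differences in each direction whose groups did not overlap (6 for the stage comparison), the 6 smallest adjusted p in each direction for the interaction, and up to 4 members per list with the smallest p. Genes named outside this rule are marked as chosen after their values were seen.

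The replicate numbers in the labels recur in every group. Deviations from the group means were compared between genotypes: same-numbered arrays correlated by 0.586, 0.475 and 0.382 across genes at E9.5, and each of these was the highest for its array. The numbers were therefore taken to pair the E9.5 samples, a pairing read from the data because the labels do not say what a number shares. The replicate block within each stage is given beside an E9.5 result, or one that sets the stages side by side, where it changes the call or moves a count by over 1.5 times, and for E7.5 alone it stands with the alternatives. The alternatives were median centring, the deposited scaling, quantile normalization within each stage, a floor at the median probe level, no filter, a filter on the mean over all arrays at the 60th percentile, the mean of a gene's probes, each comparison on its own arrays, array weights, the replicate block over all 12 arrays, a minimum of 1.5-fold, and leaving out each array in turn. Added after seeing the data were normexp background correction with an offset of 50, the replicate block within each stage, an endoderm marker score as a covariate, and a fit of the probes with no single gene name.

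The fit was tested on simulated arrays with the group means of the 13910 genes and 200 of them changed by known folds. Knockout means under test were first set to wild type, and for the stage comparison the E9.5 wild type to the E7.5 wild type. Noise was drawn from a normal distribution, independently per gene, with limma's estimate of its spread. For the E9.5 knockout comparison it recovered 100% of genes set 2-fold lower and 86% of those set 1.5-fold lower, with 8 false calls. For the E7.5 knockout comparison the shares were 100% and 86% with 5 false calls, for the interaction 100% and 42% with 13, and for the stage comparison 100% and 88% with 10. The folds were set on the measured log2 scale, so these shares do not allow for the compressed folds of dim probes. In simulated E9.5 data with 1 of the 20 lists shifted, that list was called and 0 others were. This does not test camera where list members are correlated, since the simulated genes were independent. In the real data the estimated correlation reached 0.434, in the endoderm list.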

Results

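Gene expression was measured in mouse placental tissue with and without Grhl2 at 2 stages, E7.5 and E9.5, on 12 arrays with 3 arrays per genotype and stage. The comparisons asked which genes differ between knockout and wild type at each stage, whether that difference changes between the stages, and how the wild-type tissue differs between the stages. Arrays of a genotype correlated with each other by 0.936 to 0.939 at E9.5 and by 0.894 to 0.901 at E7.5 (Spearman, across all probes), and arrays of different genotypes by 0.933 to 0.941 and by 0.897 to 0.901. Arrays of different stages correlated by 0.82 to 0.866.

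At E9.5, Grhl2 itself was 2.23-fold lower in the knockout (log2 difference -1.15, SE 0.14, adjusted p = 5.61e-04, n = 3 per group), with group means of 7.60 ± 0.25 in wild type and 6.44 ± 0.02 in knockout (log2, SD). The deposited intensities of this probe (ILMN_1257070) averaged 281.5 ± 57.9 and 104.2 ± 2.14. A second Grhl2 probe (ILMN_1226415) lay below the median probe level and differed by -0.12. The labels do not give which part of the gene was altered, so where the probes lie relative to it is unknown. The largest fall was that of Prom2, a pentaspan membrane protein of epithelial protrusions, which was 8.12-fold lower (-3.02, SE 0.19, adjusted p = 8.45e-07, means 9.36 ± 0.52 and 6.34 ± 0.13). The knockout mean of Prom2 lay below the median probe level, where folds are compressed, and its other 3 probes were near that level in all groups and differed by -0.21 to 0.08.

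Of 13910 genes tested at E9.5, 109 changed, of which 104 fell and 5 rose in the knockout. With the replicate block within each stage, 470 changed, of which 370 fell and 100 rose. The genes below are those of the fit without the block. Among the genes that fell were Tmem54, a transmembrane protein gene (-1.91, SE 0.14, adjusted p = 2.75e-06), Synb, the retroviral envelope gene syncytin-B that drives fusion of the inner syncytiotrophoblast layer (-1.46, SE 0.11, adjusted p = 3.94e-06), and Tfrc, the transferrin receptor (-1.20, SE 0.11, adjusted p = 2.04e-05). Tfrc was an abundant transcript, with group means of 11.70 ± 0.10 and 10.50 ± 0.02. Esrp2, an epithelial splicing regulator, fell by 1.27 (SE 0.11, adjusted p = 2.08e-05) and Hrc, a histidine-rich calcium-binding protein gene, by the same amount (adjusted p = 2.08e-05). Lad1, a basement membrane anchoring protein, fell by 1.30 (adjusted p = 5.61e-04), Rab15, a small GTPase of endosomes, by 1.32 (adjusted p = 0.00291), and Gm648 by 1.30 (adjusted p = 0.00661). Slc13a4, a sulfate transporter of the placenta and yolk sac, fell by 1.59 (SE 0.28, adjusted p = 0.0112). Eif2s3y, a Y-linked translation factor gene, fell by 1.36 (SE 0.24, adjusted p = 0.0105). Its second probe, with a mean below the median probe level, differed by -0.11. Serpina1b, an antitrypsin gene whose family members are nearly identical and cannot be told apart with certainty by the probe, fell by 1.35 (SE 0.24, adjusted p = 0.0109). The 5 genes that rose did so by less. They were Inmt, a methyltransferase (0.90, adjusted p = 0.0365), Myl3, a myosin light chain (0.53, adjusted p = 0.022), Trem2, a receptor of macrophages (0.51, adjusted p = 0.022), H2-Q8, a class I histocompatibility gene (0.40, adjusted p = 0.042), and Zbtb8a, a zinc finger gene (0.40, adjusted p = 0.0453). The second probes of H2-Q8 and Zbtb8a differed by 0.08 and 0.17, and the calls of Inmt, H2-Q8 and Zbtb8a were lost in 15, 14 and 16 of 25 other settings. At least 1.5-fold was reached by 74 of the called genes and 2-fold by 22.

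**Figure D1:**
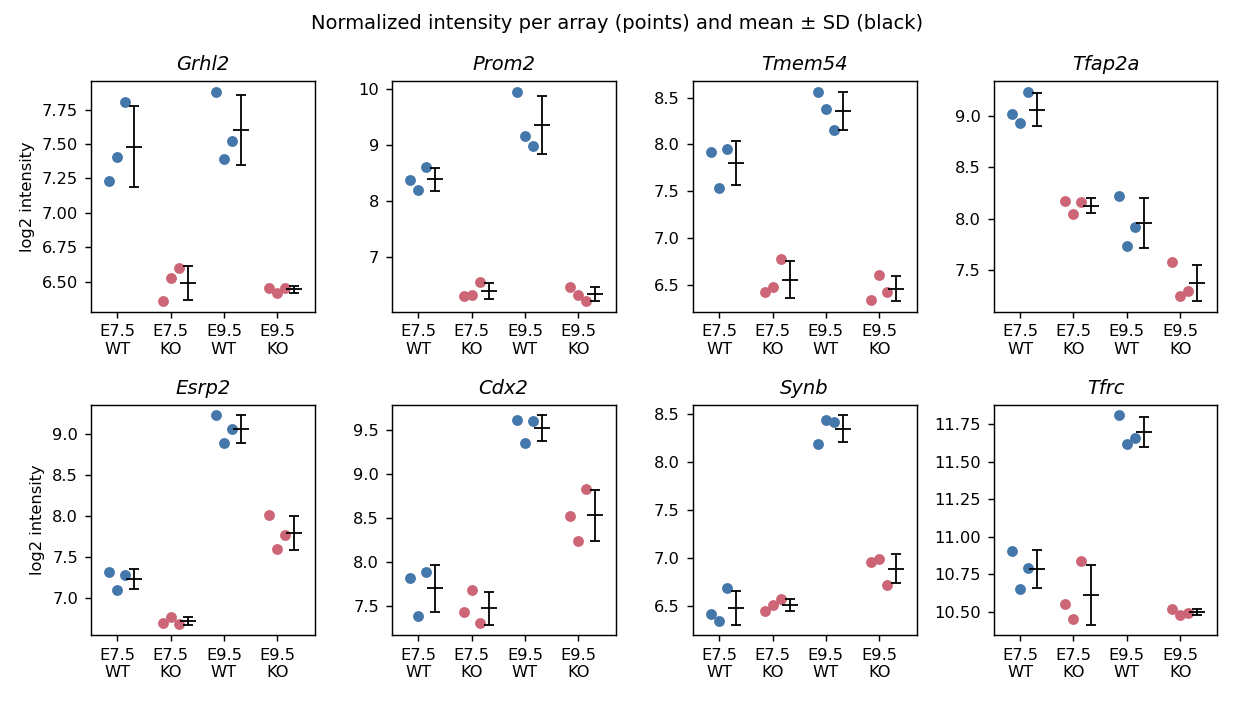
Normalized log2 intensity of 8 genes on each of the 12 arrays, with E7.5 and E9.5 wild type (WT, blue) and knockout (KO, red) as points and mean ± SD in black, on axes that differ in range and do not start at 0. Grhl2, Prom2, Tmem54 and Tfap2a were lower in the knockout at both stages, whereas the log2 difference of Synb was 0.03 at E7.5 and -1.46 at E9.5.

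Both epithelial lists had negative medians at E9.5. Of 23 measured epithelial regulators and membrane proteases, 5 fell in the test over all genes and 11 when adjusted over the list alone (median -0.38, camera adjusted p = 1.92e-12, and adjusted p = 0.0224 with an estimated correlation). Besides Esrp2, they included Rab25, a GTPase of apical recycling (-0.95, adjusted p = 0.002), Ap1m2, the epithelial adaptor subunit of basolateral sorting (-0.94, adjusted p = 0.00636), and Elf5, a transcription factor of trophoblast stem cells (-0.58, adjusted p = 0.00986). The remaining one, Spint1, an inhibitor of membrane proteases needed for labyrinth formation, was chosen after its values were seen (-0.60, adjusted p = 0.0451). Its call was lost in 14 of 25 other settings. Of 23 epithelial junction genes, 2 fell, the tight junction gene Cldn6 (-1.01, adjusted p = 0.00798) and the desmosomal gene Pkp3 (-0.73, adjusted p = 0.0424), and 6 fell when adjusted over the list alone. The calls of Cldn6 and Pkp3 were lost in 4 and 12 of 25 other settings. E-cadherin (Cdh1) differed by -0.41 (adjusted p = 0.0759) and Cldn4 by -0.43 (adjusted p = 0.105), neither past the test. With the replicate block within each stage both were called, at adjusted p = 0.0268 and 0.0279. The junction list had a median of -0.17 (camera adjusted p = 6.06e-05, and adjusted p = 0.0638 with an estimated correlation).

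The trophoblast lists had negative medians as well. Of 14 syncytiotrophoblast and labyrinth genes, 3 fell both over all genes and when adjusted over the list alone, namely Synb, Tfrc and Tfap2a, a trophoblast transcription factor (-0.58, adjusted p = 0.0424). That list had a median of -0.14 (camera adjusted p = 6.6e-06, and adjusted p = 0.0391 with an estimated correlation). Of 18 chorion and progenitor genes, 3 fell, Cdx2, the trophectoderm homeobox gene (-0.99, adjusted p = 0.0046), Elf5 and Pcsk6, a proprotein convertase (-0.70, adjusted p = 0.0244), and 6 fell when adjusted over the list alone. Esrrb, a nuclear receptor of trophoblast stem cells, differed by -0.43 (adjusted p = 0.113, and 0.0144 with the replicate block within each stage). The progenitor list had a median of -0.10 (camera adjusted p = 1.89e-05, and adjusted p = 0.0409 with an estimated correlation). Of 14 spongiotrophoblast and glycogen cell genes, 3 fell, the pregnancy-specific glycoprotein gene Psg23 (-0.72, adjusted p = 0.00561), Ceacam11 (-1.14, adjusted p = 0.0105) and Ascl2, a transcription factor of spongiotrophoblast (-0.65, adjusted p = 0.035), and 9 fell when adjusted over the list alone. Its median was -0.47 (camera adjusted p = 2.03e-10, and adjusted p = 0.0391 with an estimated correlation). Of 22 giant cell genes, 1 fell, the placenta-specific Plac1 (-0.80, adjusted p = 0.0121), and 3 fell when adjusted over the list alone (median -0.29, camera adjusted p = 1.35e-05, and adjusted p = 0.123 with an estimated correlation). Members of the placental prolactin family such as Prl3d3 (-0.72, adjusted p = 0.0839) and Prl2b1 (-0.88, adjusted p = 0.17) did not pass, but did with the replicate block within each stage (adjusted p = 1.47e-04 and 0.00194).

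Among 22 cell cycle genes at E9.5, 1 fell, cyclin E1 (Ccne1, -0.59, adjusted p = 0.0194), and 9 fell when adjusted over the list alone (median -0.21, camera adjusted p = 1.62e-10, and adjusted p = 0.0409 with an estimated correlation). Aurka, a mitotic kinase, differed by -0.36 (adjusted p = 0.0533) and Cdc6, a replication licensing factor, by -0.47 (adjusted p = 0.071), and with the replicate block within each stage both were called (adjusted p = 0.0262 and 0.0113). Of 26 imprinted genes, 3 fell, Gab1 (-0.54, adjusted p = 0.0181), Ascl2 and Sfmbt2 (-0.40, adjusted p = 0.0445), and 7 fell when adjusted over the list alone. The imprinted list had a median of -0.13 (camera adjusted p = 1.99e-06, and adjusted p = 0.0757 with an estimated correlation).

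Of the lists of markers of other cell types, 4 passed camera at E9.5 with the preset correlation and 0 of these with an estimated correlation or with fry. Of 19 visceral and parietal endoderm genes, 0 changed in limma's test over all genes, but 11 fell and 1 rose when adjusted over the list alone. Of the 19, 18 had negative differences (median -0.53, camera adjusted p = 1.66e-10, and adjusted p = 0.101 with an estimated correlation). The fibrinogen chain genes Fgg and Fga differed by -0.82 (adjusted p = 0.0762) and -0.76 (adjusted p = 0.0971), and transferrin (Trf) by -0.50 (adjusted p = 0.105), and with the replicate block within each stage all 3 were called (adjusted p = 0.0154, 0.0146 and 0.0324). Of 15 erythroid genes, 0 fell over all genes and 1 when adjusted over the list alone, with 14 negative (median -0.27, camera adjusted p = 6.28e-05, and adjusted p = 0.145 with an estimated correlation). The anion exchanger gene Slc4a1 differed by -0.99 (adjusted p = 0.0614, and 1.3e-04 with the replicate block within each stage). Of 20 endothelial genes, 0 rose over all genes and 0 when adjusted over the list alone, and 17 had positive differences (median 0.12, camera adjusted p = 9.13e-04, and adjusted p = 0.127 with an estimated correlation), such as Robo4 (0.26, adjusted p = 0.167). Of 25 leukocyte and natural killer cell genes, 0 passed either way (median 0.08, camera adjusted p = 0.0497, and adjusted p = 0.495 with an estimated correlation), and the mean turned to -0.025 without E9.5 wild-type replicate 1.

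The other 8 lists did not pass the camera test at E9.5. Their adjusted p was 0.0723 for decidua and 0.0795 for basement membrane and integrins (0.0314 and 0.047 with the replicate block within each stage), 0.121 for hypoxia and glycolysis, 0.121 for nutrient transporters, 0.346 for allantois and umbilical mesoderm, 0.413 for p53 and integrated stress response, 0.417 for mesenchyme and EMT, and 0.516 for sterol and lipid synthesis. In these lists 0 members changed over all genes, and 1 decidual, 2 transporter and 1 stress response gene fell when adjusted over the list alone. Of the 20 lists, 12 passed with the preset correlation (10 lower, 2 higher), 5 with an estimated correlation and 7 with fry.

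**Figure D2:**
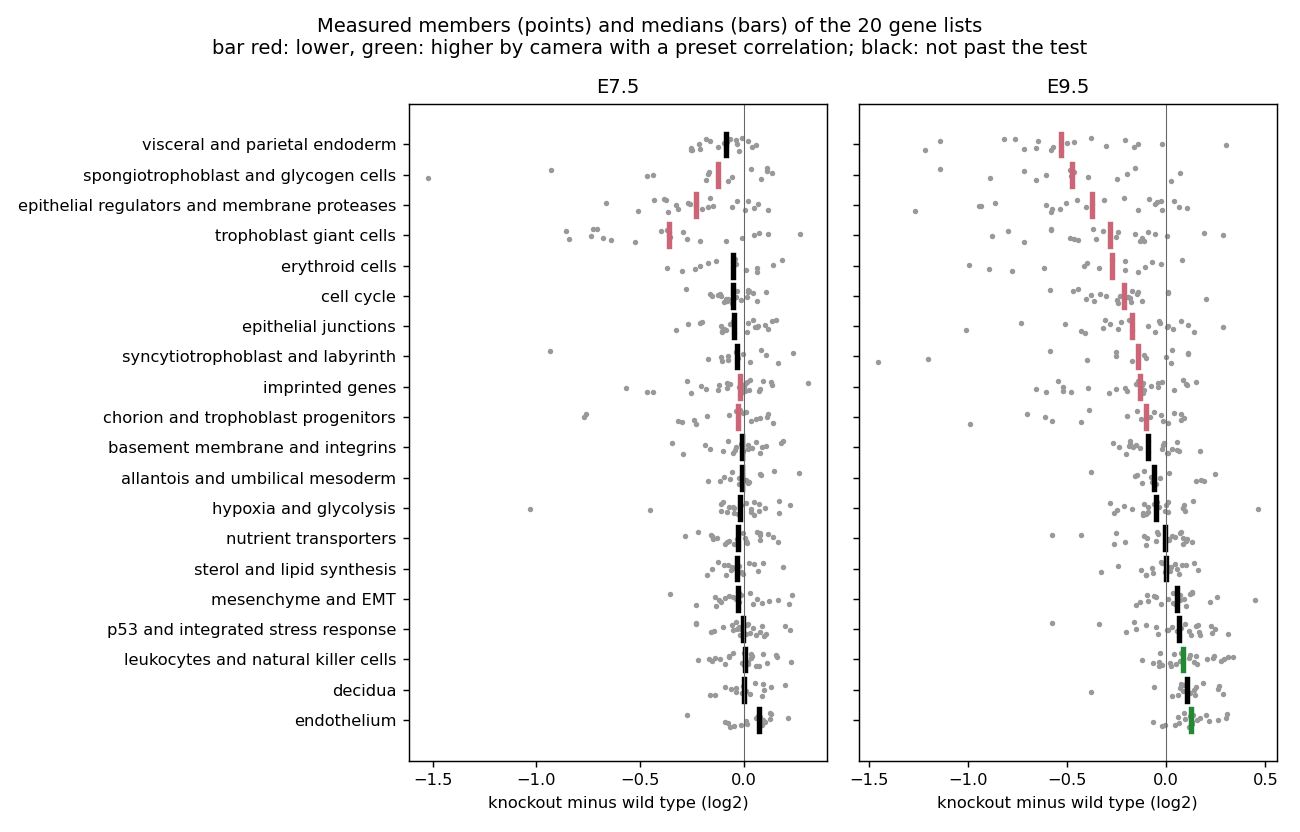
Log2 difference, knockout minus wild type, of each measured member (points) and the median (bars) of the 20 gene lists at E7.5 (left) and E9.5 (right), with bars coloured where camera with a preset correlation passed. At E9.5 the medians ran from -0.53 for visceral and parietal endoderm to 0.12 for endothelium.

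In all 109 genes called at E9.5 the 3 knockout values lay apart from the 3 wild-type values, as they did in 15.0% of all genes, where chance gives 10%. With the replicate number as a block within each stage, 470 genes changed at E9.5 (100 higher, 370 lower), including all 109. The count was 170 with median centring, 168 with the deposited scaling, 168 with quantile normalization within each stage and 30 on the E9.5 arrays alone, and with the endoderm marker score as a covariate it was 16, with Grhl2 at -1.08 (adjusted p = 0.0534). It was 55 without wild-type replicate 1, 190 without wild-type replicate 2, 62 without wild-type replicate 3 and 71 without knockout replicate 2.

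At E7.5, Grhl2 was 1.99-fold lower in the knockout (-0.99, SE 0.14, adjusted p = 0.0105, n = 3 per group), with means of 7.48 ± 0.30 and 6.49 ± 0.12. The deposited intensities of the same probe averaged 127.5 ± 23.0 and 74.3 ± 4.27, and the second probe differed by 0.03. Prom2 was 3.99-fold lower (SE 0.19 on the log2 scale, adjusted p = 2.85e-04) and Tmem54 2.37-fold lower (-1.25, SE 0.14, adjusted p = 9.37e-04). An unadjusted p under 0.05 was found for 651 of the 13910 genes tested, no larger a share than the 0.05 that chance alone gives. The genes that changed numbered 9, all lower. Besides these 3 they were Tfap2a (-0.93, SE 0.13, adjusted p = 0.00848), Utf1, a chromatin factor of pluripotent cells (-0.93, SE 0.13, adjusted p = 0.00848), Plac1 (-0.86, adjusted p = 0.0365), Trpm5, a cation channel gene (-0.66, adjusted p = 0.0251, and -0.08 for its second probe), Sfmbt2, an imprinted Polycomb gene needed in trophoblast (-0.57, adjusted p = 0.0182), and Cmtm5, a transmembrane protein gene (-0.50, adjusted p = 0.0335).

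The E7.5 giant cell list had a median of -0.36 over 22 genes (camera adjusted p = 4.87e-11, and adjusted p = 0.0892 with an estimated correlation). Of its members, 1 fell over all genes, Plac1, and 9 when adjusted over the list alone, while the prolactin family genes Prl5a1 (-0.74, adjusted p = 0.319) and Prl4a1 (-0.68, adjusted p = 0.438) did not pass over all genes. Of the 23 epithelial regulators and proteases, 0 fell over all genes and 2 when adjusted over the list alone (median -0.23, camera adjusted p = 4.41e-09, and adjusted p = 0.0645 with an estimated correlation). Among them were Prss8, a membrane protease (-0.66, adjusted p = 0.087), and Esrp2 (-0.51, adjusted p = 0.184). Of 18 chorion and progenitor genes, 0 fell over all genes and 3 when adjusted over the list alone (median -0.03, camera adjusted p = 0.00593, and adjusted p = 0.235 with an estimated correlation), with Pcsk6 at -0.76 (adjusted p = 0.0671) and Tfap2c, a trophoblast transcription factor, at -0.77 (adjusted p = 0.169). Of 14 spongiotrophoblast genes, 0 fell over all genes and 4 when adjusted over the list alone (median -0.12, camera adjusted p = 0.00593, and adjusted p = 0.474 with an estimated correlation), with Prl7b1 at -1.52 (adjusted p = 0.114) and Ceacam9 at -0.93 (adjusted p = 0.443). Of 26 imprinted genes, 1 fell both over all genes and when adjusted over the list alone, Sfmbt2 (median -0.02, camera adjusted p = 0.0304, and adjusted p = 0.726 with an estimated correlation). The other 15 lists did not pass at E7.5. Adm, the adrenomedullin gene of the hypoxia list, differed by -1.03 (adjusted p = 0.0671). The 5 lists that passed were all lower, and 0 of the 20 passed with an estimated correlation or with fry.

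In the 9 genes called at E7.5 the values of the genotypes lay apart, as they did in 9.93% of all genes, where chance gives 10%. The count was 3 with median centring, with the deposited scaling, with quantile normalization within each stage and with the floor, 4 with the mean of probes, 22 on the E7.5 arrays alone and 18 with array weights, and the Grhl2 call was lost under the first 5 of these (adjusted p from 0.0864 to 0.251). With the replicate block over all arrays the count was 22, and with the block within each stage it was 47 (2 higher, 45 lower). The count was 5 without wild-type replicate 1, 14 without wild-type replicate 2, 2 without wild-type replicate 3, 5, 3 and 5 without knockout replicates 1, 2 and 3, and 14 without E9.5 wild-type replicate 1, and the adjusted p of Grhl2 was 0.0832 without wild-type replicate 3, 0.107 without knockout replicate 1 and 0.0809 without knockout replicate 2.

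Genes lower at both stages numbered 8, all of those called at E7.5 except Cmtm5, where independent lists would share 0.0673 (Fisher's exact test, one-sided p = 6.64e-17, genes not being independent). They were Grhl2, Prom2, Tmem54, Tfap2a, Utf1, Plac1, Trpm5 and Sfmbt2. The comparisons used different arrays and shared the estimate of the spread. Of the 104 genes that fell at E9.5, 86 (82.7%) had negative differences at E7.5, against 47.6% of all genes, and their median was -0.72 at E9.5 and -0.22 at E7.5. Across all genes the differences at the stages correlated by 0.32 (Pearson) and 0.203 (Spearman), genes not being independent replicates. The count of 8 was 3 with median centring, the deposited scaling, quantile normalization within each stage or the mean of probes, 2 with the floor, 4 with the endoderm score, 13 with array weights, 17 with the replicate block over all arrays and 36 with the block within each stage. It was 4 without E9.5 wild-type replicate 3, 2 without E7.5 wild-type replicate 3, and 3 without E7.5 wild-type replicate 1 or any of the E7.5 knockout replicates 1, 2 and 3.

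**Figure D3:**
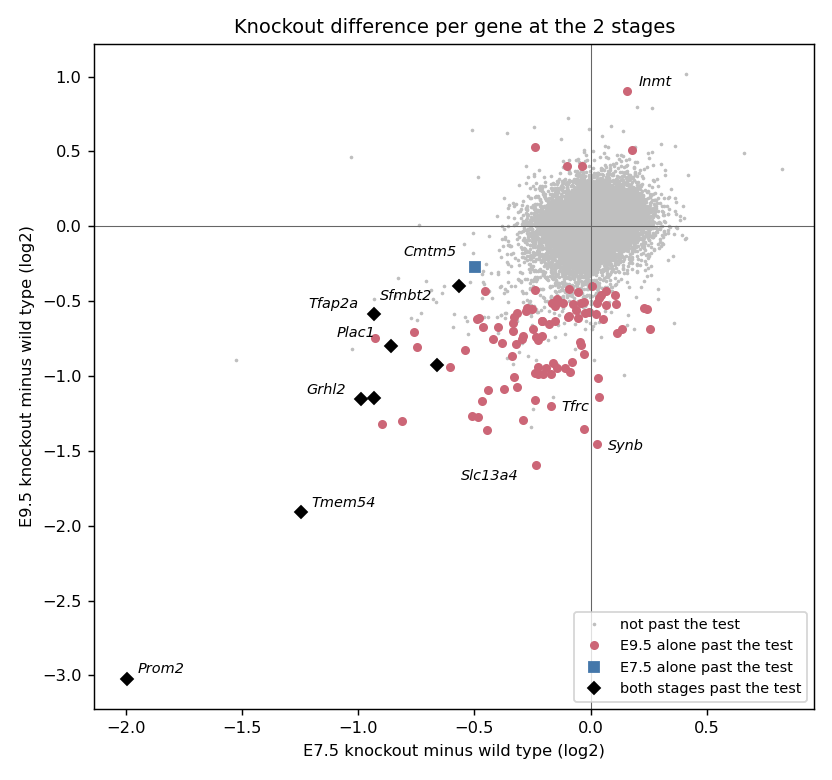
Knockout minus wild-type log2 difference of each of the 13910 tested genes at E7.5 (x axis) and E9.5 (y axis), with genes past the test at E9.5 alone in red, at E7.5 alone in blue and at both stages in black. The 8 genes past the test at both stages lie in the lower left quadrant, where Prom2 was 3.99-fold lower at E7.5 and 8.12-fold lower at E9.5. Its knockout means lay below the median probe level at both stages, where folds are compressed.

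The knockout difference of Grhl2 itself was not called different between the stages (-0.17, SE 0.20, adjusted p = 0.992). This does not show that the losses are equal, since its knockout means of 6.49 at E7.5 and 6.44 at E9.5 lay below the median probe level, where folds are compressed. The size of the gap also depended on the scaling. With the deposited scaling Grhl2 differed by -1.415 at E9.5 and -0.764 at E7.5, further apart than in the main fit. Median centring and quantile normalization within each stage each gave -1.414 and -0.764. The knockout difference of 2 genes was called different between the stages, both of the syncytiotrophoblast list. Synb differed by 0.03 at E7.5 and fell by 1.46 at E9.5, a difference of -1.48 between the stages (SE 0.15, adjusted p = 0.00104, n = 3 per group). Tfrc differed by -0.17 at E7.5 and fell by 1.20 at E9.5, a difference of -1.03 (SE 0.15, adjusted p = 0.0317). The wild-type mean of Synb at E7.5 was 6.48 ± 0.18, below the median probe level of 6.52, where folds are compressed. The next genes were the ephrin receptor gene Ephb1 (-0.82, adjusted p = 0.0616), the transporter gene Slc16a9 (-0.79, adjusted p = 0.0616) and, in the other direction, Adm (1.49, adjusted p = 0.0963) and Myl3 (0.77, adjusted p = 0.12), none of them past the test. An unadjusted p under 0.05 was found for 669 of the 13910 genes tested, no larger a share than the 0.05 that chance alone gives.

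Of the 20 lists, 9 passed camera for the difference between the stages, 8 more negative at E9.5 and endothelium more positive, and 0 passed with an estimated correlation or with fry. The adjusted p was 1.61e-05 for visceral and parietal endoderm (adjusted p = 0.374 with an estimated correlation) and 1.61e-05 for the cell cycle (adjusted p = 0.253 with an estimated correlation). It was 0.00105 for syncytiotrophoblast and labyrinth (adjusted p = 0.253 with an estimated correlation) and 0.00112 for spongiotrophoblast and glycogen cells (adjusted p = 0.253 with an estimated correlation). It was 0.00436 for epithelial junctions and for epithelial regulators (each adjusted p = 0.253 with an estimated correlation). For erythroid cells it was 0.00753, for imprinted genes 0.0179 and for endothelium 0.0384 (each adjusted p = 0.374 with an estimated correlation). Of their members, only Synb and Tfrc changed over all genes in this test. When adjusted over the list alone, 3 epithelial regulators, 2 syncytiotrophoblast, 2 spongiotrophoblast, 2 cell cycle and 1 erythroid gene had more negative differences at E9.5. The count of 2 genes was 18 with median centring, 17 with the deposited scaling or quantile normalization within each stage, 4 with the mean of probes or array weights and 21 with the replicate block within each stage. It was 17 without E9.5 wild-type replicate 2, and 1 without E9.5 wild-type replicate 1, E9.5 knockout replicate 2, E9.5 knockout replicate 3 or E7.5 knockout replicate 1.

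Between the wild-type tissues, the embryonic globin genes Hbb-y (7.92, SE 0.35, adjusted p = 3.85e-10), Hba-x (6.52, SE 0.57, adjusted p = 2.08e-07) and Hbb-bh1 (5.85, SE 0.89, adjusted p = 4.43e-05) were higher at E9.5 than at E7.5 on the log2 scale (n = 3 per group). So were Ctsj, a placental cathepsin (7.52, SE 0.23, adjusted p = 9.47e-12), and the placental prolactin family genes Prl2b1 (4.84, adjusted p = 2.72e-09) and Prl7b1 (4.17, adjusted p = 3.82e-08). Lower at E9.5 were the ribonuclease gene Rnase2a (-6.83, SE 0.18, adjusted p = 2.74e-12), Psca, a surface antigen gene (-4.25, adjusted p = 1.41e-10), Spink8, a protease inhibitor gene (-3.09, adjusted p = 6.35e-07), the collagen VI genes Col6a1 (-2.73, adjusted p = 3.32e-07) and Col6a2 (8.015-fold, adjusted p = 8.42e-08), and elastin (Eln, -2.78, adjusted p = 7.86e-07). In all, 7818 genes changed, 3522 higher and 4296 lower at E9.5, and 3563 of them by at least 1.5-fold. The split was 6943 higher and 1811 lower with median centring, and 16037 higher and 147 lower with the deposited scaling, whose array medians were apart by 0.59 on the log2 scale. The 12 genes named here kept their call in all 23 other settings, every scaling included. For differences near the size of that 0.59 stage and the authors' separate normalization cannot be told apart, and the dissected tissue differed between the stages.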

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

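The tests of a single array, of cell type markers moving apart, of the authors' normalization, of the dissection and of Xist, and the splits of the E9.5 genes, were chosen only after the result was seen, and the endoderm covariate and the probes with no single gene name were added after seeing the data. Ttr, Apoa1, Spink1, Kdm5d and Uty were chosen after their values were seen.

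Of the 109 genes called at E9.5, 104 were lower in the knockout, and the largest count among the other splits of the 6 arrays into 3 and 3 was 9 (1 of 10 splits gave as many genes, and 10 are too few for a share under 0.05). The other 3 splits that part all 3 same-numbered pairs called 0 genes. For the lists the real split gave 12 (1 of 10 splits gave as many), and the other splits gave 10, 2, 11, 10, 3, 11, 3, 2 and 3. The number of lists past camera with the preset correlation therefore hardly sets the genotypes apart from other groupings of these arrays. A single array was argued against, since at least 54 genes were called lower without any 1 array, the fewest without wild-type replicate 1. For a loss of trophoblast cells alone, the endothelium and endoderm medians lay 0.656 apart (95% bootstrap interval 0.427 to 0.79). That interval resampled genes within the lists and not arrays, and the endoderm scores of the genotypes overlapped. A loss of trophoblast cells alone therefore remains open. With the endoderm score as a covariate the median of the genes called lower went from -0.723 to -0.658 (quartiles -0.874 and -0.489). Of the 109 calls 16 were left, as the median SE grew from 0.121 to 0.158. The score thus accounted for little of the fall of the called genes. In all of them the genotypes lay apart while the endoderm scores overlapped, so genes that follow the score were unlikely to be called. This fit therefore cannot decide whether unevenly carried yolk sac endoderm was a cause. The authors' normalization cannot be told apart from a biological effect of the knockout, because equal distributions hold the median of all genes near 0 (0.0132).

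The endoderm list was lower in the E9.5 knockout by a median of -0.53 and the erythroid list by -0.27 (adjusted p = 0.101 and adjusted p = 0.145 with an estimated correlation, neither past the test), and 1 of the 19 endoderm genes, Sox17, is also on the endothelium list. The abundant endoderm transcripts Ttr, Apoa1 and Spink1 had wild-type means of 11.89, 11.72 and 10.94 and differed by -0.58, -1.22 and -1.14, none past the test over all genes. The mean endoderm score per array was 0.51, -0.20 and 0.44 in wild type and -0.32, -0.09 and -0.34 in knockout (exact two-sided permutation p = 0.2, where 0.1 is the smallest possible). The ranges overlapped by 0.108 (lowest wild-type minus highest knockout score -0.108), and for replicate number 2 the knockout score was the higher. The permutation took no account of the replicate numbers. The mean erythroid score was 0.53, 0.02 and -0.01 in wild type and 0.13, -0.50 and -0.17 in knockout. It was lower in the knockout for each replicate number, but its ranges overlapped as well. Uneven dissection of yolk sac and blood therefore cannot be told apart from fewer such cells or lower expression in the knockout. With the score as a covariate the erythroid median went from -0.27 to -0.07, that of the epithelial regulators from -0.38 to -0.27 and that of the epithelial junctions from -0.171 to -0.113, while the others moved away from 0: syncytiotrophoblast from -0.142 to -0.192, chorion from -0.104 to -0.123, spongiotrophoblast from -0.473 to -0.501, giant cells from -0.286 to -0.292, cell cycle from -0.214 to -0.241 and endothelium from 0.125 to 0.153.

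The Y-linked gene Eif2s3y was 8.31, 7.57 and 7.72 in the E9.5 wild-type arrays and 6.23, 7.02 and 6.26 in the knockout arrays, and its call was lost in 5 of 25 settings, while its second probe, near the median probe level, differed by -0.11. A candidate explanation is a lower share of male embryos in the knockout samples, which would raise Xist. The Xist difference was 0.302 (SE 0.137, adjusted p = 0.44), in the direction it needs but not past the test, so it cannot be told apart from a lower level of Eif2s3y per cell. The probes of Kdm5d and Uty lay near the median probe level and could not add to this.

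The E9.5 minus the E7.5 knockout difference was -1.48 for Synb and -1.03 for Tfrc, each past the test of the difference itself, and Synb kept this call in all 23 other settings while Tfrc lost it in 9 of 23 (adjusted p up to 0.11). The E7.5 wild-type mean of Synb lay below the median probe level, so a fall at E7.5 could hardly have been seen. By the list test of that difference, which 0 of the lists passed with an estimated correlation (adjusted p = 0.253 to adjusted p = 0.374) or with fry, the median over members was -0.086 for epithelial junctions, -0.12 for epithelial regulators and membrane proteases, -0.14 for syncytiotrophoblast and labyrinth and -0.22 for spongiotrophoblast and glycogen cells. It was 0.058 for endothelium, -0.22 for erythroid cells, -0.40 for visceral and parietal endoderm, -0.17 for the cell cycle and -0.063 for imprinted genes. Of 100 splits of both stages, 10 gave as many genes as the 2 of the real one, the highest other 89. Each of the other 9 kept the genotype grouping of at least 1 stage, and that with 89 kept both with the labels of 1 stage exchanged, so they carry the knockout effect itself and the tally decides nothing about chance. The 85 splits that kept neither grouping gave at most 1 gene. For the genes called at both stages the real value was 8 and the highest other 0 (1 of 100 splits), a share under 0.05. Splits that mix the genotypes put the knockout effect into the spread, which can lower their counts, so this does not exclude chance.

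Among the 4250 probes tested that name no gene or several, 32 were called in the E9.5 knockout (1 higher, 31 lower) and 1 in the E7.5 knockout (lower).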

How the results depend on the processing

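The normexp correction, the replicate block within each stage, the endoderm covariate and the fit of probes with no single gene name were chosen only after the result was seen. For the stage comparison, 12 of 12 named genes kept their call in all 23 settings run for it. The replicate block within each stage and the endoderm covariate were not run for that comparison. Of the other named genes, 8 of 46 called at E9.5 kept their call in every setting run for them (Prom2, Tmem54, Synb, Lad1, Hrc, Esrp2, Tfrc and Utf1). So did 1 of 9 at E7.5 (Tmem54) and 1 of 2 for the difference between stages (Synb). Of the lists, 5 of 12 at E9.5 (epithelial regulators, syncytiotrophoblast, chorion, spongiotrophoblast and cell cycle) and 0 of 5 at E7.5 kept theirs in all 26 settings run for lists. The endoderm covariate was not among these 26, since no list test was run with it. At least 10 of 25 settings lost the E9.5 calls of Zbtb8a (16), Inmt (15), H2-Q8 (14), Spint1 (14), Llgl2 (13), Pkp3 (12), Tfap2a (12), Sfmbt2 (12), Col17a1 (12), Ascl2 (11) and Cdc25a (11), and the E7.5 calls of Plac1 (11), Cmtm5 (11) and Trpm5 (10). The cause was not tested except where stated. Without background subtraction, probes near the median level show compressed folds.

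With median centring the genes called numbered 170 at E9.5, 3 at E7.5, 18 for the difference between stages and 3 at both stages, and Grhl2 at E7.5 was -0.76 (adjusted p = 0.092). With the deposited scaling they were 168, 3, 17 and 3, with 16184 between the wild-type stages and Grhl2 at E7.5 -0.76 (adjusted p = 0.0864). Quantile normalization within each stage gave 168, 3, 17, 3 and 16183, with Grhl2 at -0.76 (adjusted p = 0.0865). Of the 109 genes called at E9.5, 108 were kept under each of these scalings, but 59 with the floor (97 called), 63 with the mean of probes (74 called), 30 on the E9.5 arrays alone and 16 with the endoderm covariate. Without 1 array from 52 (without E9.5 wild-type replicate 1) to 103 were kept, 58 without E9.5 wild-type replicate 3 and 62 without E9.5 knockout replicate 2. The floor gave 3 genes at E7.5 and 2 at both stages, Grhl2 at E7.5 -0.94 (adjusted p = 0.162) and Synb at E7.5 turned to -0.038. With no filter 3 lists passed at E7.5. The mean of probes gave 4 genes at E7.5, 4 for the difference, 3 at both stages, 3 lists at E7.5 and Grhl2 at E7.5 -0.48 (adjusted p = 0.251), since its second probe was dim. Across all settings the adjusted p of Grhl2 at E7.5 ran from 9.4e-05 to 0.251.

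Each comparison on its own arrays, with fewer arrays behind the spread, gave 30 genes at E9.5 in place of 109. At E7.5 it gave 22 in place of 9, a rise that fewer arrays alone would not give. The contrast between 109 and 9 genes therefore depends on the estimate of the spread shared by the stages. Array weights gave 18 at E7.5, 4 for the difference and 13 at both stages. At E7.5 same-numbered arrays correlated by 0.0559, 0.169 and 0.103, less than at E9.5, although there too each array correlated best with its own number. Whether the E7.5 samples of a number share anything is unknown. The replicate block over all arrays gave 161 genes at E9.5, 22 at E7.5 and 17 at both stages. Within each stage the block gave 470, 47, 21 for the difference and 36 at both stages. Of the E9.5 lists, 12 and 14 passed with these blocks. Apart from the calls gained within each stage, the block changed no call of a gene or list named at E9.5 there.

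A minimum of 1.5-fold left 3563 genes between the stages, by construction. An estimated correlation left 5 lists at E9.5 and 0 at E7.5, and fry 7 and 0. The endoderm covariate left 16 genes at E9.5 and 4 at both stages, with Grhl2 at E9.5 -1.08 (adjusted p = 0.0534). The probes with no single gene name gave 32 at E9.5.

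Leaving out each array in turn, which keeps 2 arrays in a group, gave 55 (without E9.5 wild-type replicate 1) to 190 genes (without E9.5 wild-type replicate 2) at E9.5 and 2 (without E7.5 wild-type replicate 3) to 14 at E7.5. The ranges were 1 to 17 for the difference, 7045 to 7874 between the stages, 2 to 11 at both stages, 11 to 14 lists at E9.5 and 3 (without E7.5 wild-type replicate 1 or knockout replicate 2) to 6 at E7.5. Grhl2 ranged from -1.26 to -1.01 at E9.5 and from -1.11 to -0.83 at E7.5. Synb at E7.5, which was not called, ranged from -0.037 (without wild-type replicate 2) to 0.13, and was also negative without wild-type replicate 1 (-0.0057) and knockout replicate 3 (-0.00068). The mean of the leukocyte list ranged from -0.025 without E9.5 wild-type replicate 1 to 0.21 and it kept its call in 6 of 26 settings. Over the settings that left out no array, the named genes gave 1143 results on the same side of the test, 143 that lost their call and 78 that gained one, and over those that left out 1 array 1088, 177 and 28.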

Other observations

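The genes and groups in this part, other than those of the delay test and of the splits, were chosen after their values were seen, as were the splits of the E7.5 genes and the X chromosome test.

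Further single genes that fell at E9.5 were on none of the lists. Utf1 fell by 1.15 (SE 0.13, adjusted p = 2.21e-04), the DNA methyltransferase gene Dnmt3b by 0.75 (adjusted p = 0.00643), the zinc finger gene Sall4 by 0.74 (adjusted p = 0.0189) and Dppa4 by 0.60 (adjusted p = 0.00834). Also lower were the uracil glycosylase gene Ung (-0.79, adjusted p = 0.00149), E2f2 (-0.56, adjusted p = 0.00225), Mybl2 (-0.56, adjusted p = 0.0268) and the phosphatase gene Cdc25a (-0.52, adjusted p = 0.032). The calls of Cdc25a, Sall4, Mybl2 and Dppa4 were lost in 11, 8, 8 and 5 of 25 other settings. Of these 8 genes, Utf1 fell at E7.5 as well, and the differences between the stages were not called for any of them.

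Of other genes on none of the lists, the kinase gene Ripk4 fell by 0.69 (adjusted p = 0.00414), stratifin (Sfn) by 0.67 (adjusted p = 0.00716), the polarity gene Llgl2 by 0.63 (adjusted p = 0.0373) and the hemidesmosomal collagen gene Col17a1 by 0.60 (adjusted p = 0.035). The calls of Llgl2 and Col17a1 were lost in 13 and 12 of 25 other settings. Of the Grhl2 paralogs, the probes of Grhl1 differed at E9.5 by -0.40 and -0.09 and those of Grhl3 by 0.06 and 0.09. At E7.5 the same probes differed by -0.06, 0.20, -0.17 and -0.13.

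Of the 104 genes that fell at E9.5, 10 lie on the X chromosome, against 479 of the 13910 genes tested and 3.58 expected (odds ratio 3.02, Fisher's exact test, two-sided p = 0.00309, genes not being independent). The median difference of all X-linked genes was 0.0112.

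A hypothesis was that the knockout placenta may be delayed at E9.5, so that its differences run against the change from E7.5 to E9.5. The slope of the E9.5 knockout difference on the stage difference, taken as the mean of all 6 E9.5 arrays minus that of all 6 E7.5 arrays, across 13910 genes was -0.0832, with a correlation of -0.287. The test set before this slope was seen asked for a larger size than in every other split of the 6 arrays, and it was met by a small margin, the highest other being 0.0822. The 10 splits are too few for a share under 0.05, and a split of the same samples with nearly the same slope leaves the hypothesis open.

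For the genes called at E7.5, the real split gave 9 and the highest other 1 (1 of 10 splits), and for the lists at E7.5 the real split gave 5 and the highest other 8 (3 of 10 splits). Between the wild-type stages the real split gave 7818 genes and the highest other 0 (1 of 10 splits). In each case 10 splits are too few for a share under 0.05.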
